A study of Mus musculus with 6 samples.

How the data were processed

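The samples were 6 pools of stria vascularis RNA, 3 wild type and 3 Esrrb mutant, each from 10 mice and each on 1 Affymetrix array. The design text speaks of pooled inner ears and the sample labels of stria vascularis; the labels are followed here. The deposited values are log2 expression values per probe set, made with RMA, per the submitters' processing notes; its version and settings are not given in the sources used here. The log2 scale was read from the values, which run from 2.33 to 14.6. The values were used as deposited.

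The deposited values differ by pair. Exactly equal values on 2 arrays occurred for 15406, 1185 and 1398 probe sets in pairs 1, 2 and 3 of same-numbered arrays and for 0 probe sets in any other pair of arrays, and array medians matched within pairs and differed between them. The pairing comes from these replicate numbers in the labels and from this check: across probe sets, deviations from the genotype means correlated at 0.879, 0.818 and 0.746 in pairs 1 to 3, above the limit of 0.1 set for pairing. The numbers were therefore used to pair the samples, though processing each pair separately could also raise these correlations. Whether RMA was run on each pair separately is not given in the sources used here, though the equal values and medians point to it. In pair 1, 34.2% of probe sets had a difference of exactly 0.

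Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with its default prior, two-sided), with Benjamini-Hochberg adjustment over 45037 probe sets and a threshold of 0.05. The planned fit had the genotype alone; the paired fit added the replicate number as a block. The table held 45101 probe sets, of which 64 control probe sets were left out and no filter on level was used. Of those tested, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none and are unnamed here. A gene was represented by the probe set with the highest mean over the 6 arrays, which gave 18193 genes. Symbols were checked through gene identifiers against a RefSeq gene table of assembly GRCm38.p6, which matched 34754 probe sets and changed 0 symbols. That table also gave the older symbols of listed genes, the chromosome of each gene and the genes that neighbour Esrrb. No coordinates are printed because the files name no genome build.

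A total of 32 gene lists was fixed before the data were examined, along with the tests and the rule for named genes; 31 were tested and the sex chromosome genes served as a check. Of the listed genes 35 were not matched and are not analysed here, and 5 were matched through an older symbol. Lists were tested with limma's camera with a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry. The rule named Esrrb, Esrra and Esrrg, the 12 genes with the largest rise and fall among those that passed with non-overlapping genotypes, or the 5 with the smallest p where fewer than 5 passed in a direction, and from each list up to 4 members that passed or else the 2 with the highest level. After the pairing was seen, the same rule was applied to the paired fit, with the same sign in 3 pairs in place of non-overlap. All genes named outside this rule were chosen after their values were seen.

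The fits were tested on simulated data with the same number of probe sets, built on the mean of each real pair. Normal noise was added, with variances drawn from the distribution that the paired fit estimated. The paired model was thus true of the simulated data by construction, and the equal values within pairs were not reproduced. Recovery there does not show that paired p-values hold for the real arrays. Of 100 probe sets changed by 1 on the log2 scale, the paired fit recovered 83 and the unpaired fit 0, and of 100 changed by 2 it recovered 99 and 0, with 8 false calls in the paired fit and 0 in the unpaired. A list shifted by 0.5 was called in both, with 0 of 30 other lists. The simulated noise was independent between genes, whereas the estimated correlation in the real data reached 0.93, for endothelial markers in the unpaired fit. The simulation therefore does not show how often lists of correlated genes are called falsely. Alternatives were a filter on level, quantile normalization and median centring across all arrays, eBayes with trend and robust options, array weights, the replicate block, leaving out each array, the mean of a gene's probe sets, leaving out cross-hybridising probe sets, stricter thresholds, other list tests and other windows around Esrrb. The same alternatives within the paired fit, and leaving out each pair, were chosen after seeing the data.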

Results

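Gene expression was measured in the stria vascularis of mice carrying a conditional mutation of Esrrb and in wild-type controls. The stria vascularis is the epithelium of the cochlear lateral wall that secretes potassium into endolymph, and Esrrb (named Errb or Nr3b2 in the labels) encodes the orphan nuclear receptor estrogen-related receptor beta. Total RNA from 6 pools of 10 mice, 3 pools per genotype, was hybridised to 1 Affymetrix array each. An age of postnatal day 3 to 5 is given for wild-type replicate 1 and for no other pool. The comparison asked which transcripts the mutation raised or lowered in this tissue. The pools are separate samples only as far as the labels say, so p-values measure the spread between these 6 samples. With 3 arrays per genotype, the number of arrays limits the precision, and an exact permutation test could not go below p = 0.1. Array medians were 6.07, 6.95 and 6.42 (log2) in wild-type replicates 1 to 3 and 6.08, 6.94 and 6.38 in the mutant replicates of the same numbers. Differences are given as mutant minus wild type on the log2 scale, as the mean ± SD of the 3 same-numbered pairs (n = 3). Adjusted p-values are from limma, first without the pairs and then, as the paired fit, with the replicate number as a block.

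The best expressed probe set of Esrrb was at a similar level in both genotypes. It is of the class left out as cross-hybridising in 1 of the alternatives. This probe set averaged 10.08 ± 0.47 (SD, n = 3) in wild type and 10.01 ± 0.26 in the mutant, a difference of -0.07 ± 0.21 with adjusted p = 1 unpaired and 0.856 paired, and a 95% interval of -0.32 to 0.18 in the paired fit. The next probe set by level differed by -0.18 ± 0.43. The lowest differed by -0.42 ± 0.46 and was lower in all 3 pairs (-0.049, -0.29 and -0.93). Its values were 4.90 and 4.85 on the arrays of pair 1, against 7.21 to 8.15 on those of pairs 2 and 3. None of the 3 passed in either fit. Where these probe sets lie relative to the deleted part of the gene is not given in the sources used here, so they check nothing about the genotype labels. The related receptors Esrra (-0.18 ± 0.17) and Esrrg (-0.19 ± 0.17) did not pass either (adjusted p = 0.742 and 0.730, paired).

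Kcne1, which encodes the accessory subunit of the potassium channel at the apical membrane of strial marginal cells, was the gene most strongly lowered in the mutant. It fell from 9.70 ± 0.48 to 5.39 ± 0.63, a 19.9-fold difference of -4.32 ± 0.30 (adjusted p = 0.0071 unpaired, 0.00373 paired), and its second probe set fell by 4.66 on the log2 scale. On the mutant arrays the 2 probe sets lay at the 21.8 to 38.2 and the 7.89 to 15.7 percentile of all probe sets. Signal over background is not given, so the size of the fold is uncertain. Dnase1, a secreted endonuclease, fell by 3.31 ± 0.60, and Aldh1a2, a retinoic acid synthesising enzyme, fell by 2.73 ± 0.18 in the paired fit (adjusted p = 0.0388 and 0.0038; 0.158 for both unpaired). Slitrk4 (2.41 ± 0.09) and Igsf1 (2.26 ± 0.08), both coding for membrane proteins, rose 5.30-fold and 4.80-fold in the paired fit (adjusted p = 0.00373 for both; 0.158 and 0.762 unpaired).

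In the unpaired fit 3 of 45037 probe sets passed, 1 higher and 2 lower in the mutant, and Kcne1 was the only gene of 18193 to pass by its best expressed probe set. With quantile normalization of all arrays or median centring, 1 higher and 1 lower probe set passed instead. Under these 2 settings Igsf1 was the only gene to pass (adjusted p = 0.0228 and 0.0180, within 0.00244 to 1 over its 13 unpaired alternatives other than array weights), and the best expressed probe set of Kcne1 did not (adjusted p = 0.0887 and 0.0793, within 1.89e-14 to 0.0887 over its own 13), while its second probe set did (0.0105 and 0.0117). At an unadjusted p under 0.05 the unpaired fit held 94 probe sets, 19 higher and 75 lower, against 2252 from chance alone if the arrays were independent. Same-numbered arrays were correlated, so variation between pairs stayed in the unpaired error and made p-values of single probe sets too large. The shortfall is therefore no measure of how few probe sets changed. In the paired fit 42 probe sets passed, 5 higher and 37 lower. At an unadjusted p under 0.05 its balance was the other way, with 1853 higher and 1381 lower of 3234 probe sets, against the same 2252. Counted by the best expressed probe set of each gene, 3 higher and 24 lower genes passed; another 1 and 4 genes passed by a different probe set alone and are not in these counts. The probe set with the largest rise (3.56 ± 0.09) passed in both fits but is assigned several symbols and is left unnamed. It is of the class left out as cross-hybridising in 1 of the alternatives. It did not pass unpaired after quantile normalization or median centring, where the 1 higher probe set was that of Igsf1. When any replicate number was left out of the paired fit, 1 residual degree of freedom remained, and 7, 0 and 0 probe sets passed without replicates 1, 2 and 3.

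By their best expressed probe sets, the 12 genes that fell furthest in the paired fit included Kcne1, Dnase1 and Aldh1a2. Atp13a5 (-1.86 ± 0.26) and Kcnq1 (-1.67 ± 0.17) were also among them and are described with their lists below. The other 7 included Ehd3, an endocytic trafficking protein (-2.02 ± 0.21), and Rspo3, a secreted enhancer of Wnt signalling (-1.92 ± 0.27). Rnf152, a ubiquitin ligase (-1.86 ± 0.39), and Nfe2l3, a basic leucine zipper transcription factor (-1.76 ± 0.32), were 2 more. Nipal1, a magnesium transporter gene (-1.72 ± 0.07), Tmem45b (-1.69 ± 0.15) and Ptgds, the prostaglandin D synthase gene (-1.70 ± 0.23), fell as well. None of these 7 passed in the unpaired fit, where each had an adjusted p of 1. Tacr3, picked after its values were seen, fell further than these 7, but by a less expressed probe set alone. That probe set differed by -2.21 ± 0.27 (limma adjusted p = 0.0193 paired, 0.218 unpaired). S100a6, which encodes a calcium-binding protein, was the third gene to rise (1.45 ± 0.22, adjusted p = 0.0388, paired). The genes with the next smallest p in that direction did not pass: Camk2d differed by 0.91 ± 0.11 (adjusted p = 0.0506), Hey2 by 0.76 ± 0.05 (0.0630), and in the unpaired ranking Rbfox1 by 1.87 ± 0.50 and Thbs4 by 1.70 ± 0.60. Of the 27 genes, 14 had several probe sets, and in all 14 the mean differences of these had the same sign. All probe sets of a gene passed in 3 of the 14, Adm, Kcne1 and Ptgds. Several had much weaker probe sets: Igsf1 at 0.37 and 0.04, and Nfe2l3 at -0.50 and -0.03. Nipal1 had another at -0.55, Rspo3 at -0.44 and Slitrk4 at 1.38.

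**Figure D1:**
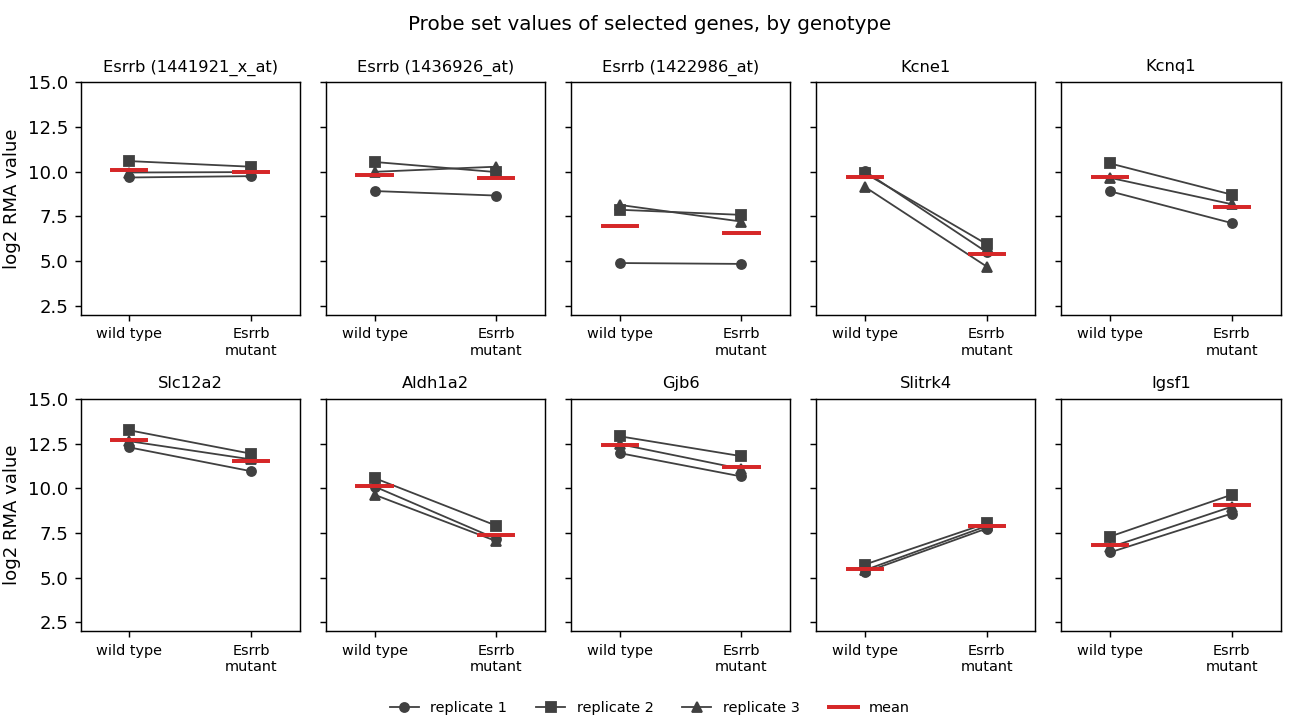
Log2 RMA values (vertical axis) of 10 probe sets in wild-type and Esrrb mutant stria, with a symbol for each replicate number, lines joining same-numbered arrays and red bars for the means of 3 arrays. The 3 lines of Kcne1 drop by 3.97 to 4.52, those of Igsf1 climb by 2.17 to 2.34, those of the lowest Esrrb probe set all point down, and those of its other 2 probe sets go both ways.

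The genes for potassium secretion stood out as a group. All 7 measured members of that list were lower in the mutant, with a list median of -1.24 ± 0.14 over the 3 pairs (camera adjusted p = 4.14e-61 unpaired and 2.24e-16 paired). With an estimated correlation the unpaired call held (adjusted p = 0.0472) and the paired call was lost (adjusted p = 0.386 with an estimated correlation). Kcne1, Kcnq1, the pore-forming partner of Kcne1 (-1.67 ± 0.17), and Slc12a2, the basolateral sodium-potassium-chloride cotransporter (-1.22 ± 0.18), fell in the paired fit, and Kcne1 alone in the unpaired fit. When adjusted over the list alone, 6 of the 7 passed in the paired fit and 4 in the unpaired fit. Of the members named after their values were seen, the chloride channel subunit gene Bsnd (-1.05) passed over the list but not over all probe sets. The sodium pump subunit gene Atp1b2 did so by its best expressed probe set (-1.40), while another of its probe sets (-1.49) passed over all probe sets in the paired fit.

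Marginal cell markers, which share several members with that list, had a median of -0.58 ± 0.15 (camera adjusted p = 2.56e-50 unpaired and 4.37e-15 paired; adjusted p = 0.0829 and 0.408 with an estimated correlation). Of 15 measured, 4 fell in the paired fit, namely Kcne1, Kcnq1, Slc12a2 and Atp13a5, a P-type ATPase gene (-1.86 ± 0.26), and none rose. When adjusted over the list alone, 10 passed in the paired fit, 9 lower and 1 higher, and 5 in the unpaired fit. Basal cell markers had a median of -0.22 ± 0.10 (adjusted p = 2.26e-06 unpaired, 0.000315 paired; 0.461 and 0.524 with an estimated correlation). In the paired fit Gjb6, the connexin 30 gene, fell by 1.27 ± 0.14, the other 6 of 7 basal cell markers did not pass, and 3 passed when adjusted over the list alone. Gjb2, its connexin 26 partner, differed by -0.72 ± 0.32 without passing over all probe sets.

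Pigment cell genes were lower without any single gene passing over all probe sets. The 19 markers of strial intermediate cells and melanocytes had a median of -0.46 ± 0.02, with pair medians of -0.46, -0.45 and -0.48 (camera adjusted p = 1.15e-23 unpaired, 2.29e-13 paired; adjusted p = 0.329 and 0.408 with an estimated correlation). In the paired fit 12 of the 19 passed when adjusted over the list alone, all lower, against 0 unpaired. Dct, a melanin synthesis enzyme gene and the best expressed member, differed by -0.68 ± 0.08 (adjusted p = 0.0870). Among the 12, the tyrosinase gene Tyr (-1.13) and Mlana (-0.91) had the largest differences, whereas Sox10 (0.09), Kit (-0.12) and Tyrp1 (0.04) were not among them; these 5 are named after their values were seen.

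The lists of 4 other cell groups had medians above 0 and passed with the preset correlation in both fits, and these calls were lost with an estimated correlation. Neuron markers had a median of 0.52 ± 0.46, with 1.05 in pair 1 and 0.27 and 0.24 in the others (camera adjusted p = 1.36e-21 unpaired, 1.86e-05 paired; 0.0829 and 0.524 with an estimated correlation). Nefl, a neurofilament gene named after its values were seen, was 4.63 higher in the mutant of pair 1 and 0.82 and 0.54 higher in the others. Schwann cell and glial markers, a list that did not pass, also had their highest median in pair 1 (0.41, against -0.04 and 0.0005). The cause of these differences in pair 1 was not tested. Pair 1 also stood apart in RNA quality: the difference between the 3' and 5' control probe sets of Gapdh was 2.28 in wild type and 2.57 in the mutant there. It was 0.21 and 0.16 in pair 2, and -0.04 and 0.51 in pair 3. For Actb it was 1.01 and 1.35 in pair 1, 0.52 and 0.47 in pair 2, and 0.18 and 0.49 in pair 3. The gap was thus wider in the mutant in pairs 1 and 3, where RNA quality was not balanced between the genotypes. Macrophage markers had a median of 0.22 ± 0.23 (adjusted p = 0.00101 unpaired, 0.00109 paired; 0.776 and 0.580 with an estimated correlation), tectorial membrane and supporting cell genes 0.18 ± 0.20 (1.92e-08, 0.00131; 0.461 and 0.524), and spindle, root and outer sulcus cell markers 0.14 ± 0.13 (0.00183, 0.00727; 0.733 and 0.531). The macrophage list median was -0.03 in pair 1 and 0.41 and 0.27 in pairs 2 and 3. No member of these 4 lists passed over all probe sets. Otog, a tectorial membrane gene, differed by 1.08 ± 0.33 (adjusted p = 0.141, paired) and Anxa1, a marker of spindle and root cells, by 0.79 ± 0.17 (0.108).

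Endothelial markers were lower in 12 of 12 genes, with a median of -0.21 ± 0.04 (camera adjusted p = 0.00320 unpaired, 0.000120 paired; 0.776 and 0.408 with an estimated correlation), and none passed singly. Leaving out 1 array moved the unpaired endothelial median between -0.56 without wild-type replicate 1 and 0.20 without mutant replicate 1, where the median of all probe sets was -0.19 and 0.19. Erythroid markers had a median of -0.10 ± 0.09 (0.0278, 0.00799; 0.776 and 0.524 with an estimated correlation). Cartilage and bone markers (0.11 ± 0.08) and spiral ligament fibrocyte markers (-0.05 ± 0.11) passed unpaired (adjusted p = 0.00640 and 0.00750; both 0.776 with an estimated correlation) and not paired (both 0.104). Ibsp, a bone matrix gene named after its values were seen, was 3.85 higher in the mutant of pair 1 against 0.16 and -0.07 in the others. The same 2 settings put the unpaired cartilage and bone median at -0.24 and 0.54 and the fibrocyte median at -0.35 and 0.39. The fibrocyte list shares Gjb6 and Gjb2 with the basal cell list, and Gjb6 was its only member to pass over all probe sets, in the paired fit; 2 members, both lower, passed there when adjusted over the list alone. Chondrocyte collagens in the dissected tissue, such as Col2a1 (0.04 ± 0.31), were near equal in the genotypes.

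Genes of mitochondrial metabolism were slightly lower. All 20 oxidative phosphorylation genes had negative differences, with a median of -0.16 ± 0.05 (camera adjusted p = 1.61e-07 unpaired, 6.00e-10 paired; 0.733 and 0.524 with an estimated correlation). None passed over all probe sets, and 2 passed when adjusted over the list alone in the paired fit, Cox7a1 (-1.03) and Atp5b (-0.38), named after their values were seen. Fatty acid oxidation and tricarboxylic acid cycle genes had a median of -0.13 ± 0.09 (0.000753, 2.77e-06; 0.776 and 0.408 with an estimated correlation), with 0 of 21 passing by either adjustment. Cell cycle genes were higher in 21 of 22, with a median of 0.19 ± 0.21 (9.96e-08, 4.48e-07; 0.359 and 0.524 with an estimated correlation). Their pair medians were 0.06, 0.09 and 0.43. Mki67, a proliferation marker, differed by 0.41 ± 0.33 (adjusted p = 0.609, paired) and did not pass.

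In all, 15 of 31 gene lists passed in the unpaired fit with the preset correlation and 13 in the paired fit. With an estimated correlation 1 and 0 passed, and with limma's fry, which tests whether a list moves 1 way on balance, 0 and 1, the latter potassium secretion (adjusted p = 0.0207). Divisions of the 6 arrays that mixed the genotypes gave up to 17 lists unpaired and 10 paired. The other 16 lists did not pass in either fit, with adjusted p from 0.0549 to 0.889 unpaired. They were proton pump ionocyte genes, markers of Reissner membrane, hair cells, skeletal muscle, pericytes and smooth muscle, neutrophils, and Schwann cells and glia, epithelial junctions and keratins, otic developmental transcription factors, estrogen-related receptors and coregulators, glycolysis and hypoxia, p53 and apoptosis, endoplasmic reticulum stress, immediate early genes, interferon response, and extracellular matrix and basement membrane. Their medians lay between -0.06 for proton pump ionocyte genes and 0.15 for Reissner membrane markers. No member of the 16 passed over all probe sets. The sign of median, mean or test differed for Reissner membrane, proton pump ionocyte, skeletal muscle, neutrophil, p53 and interferon genes.

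**Figure D2:**
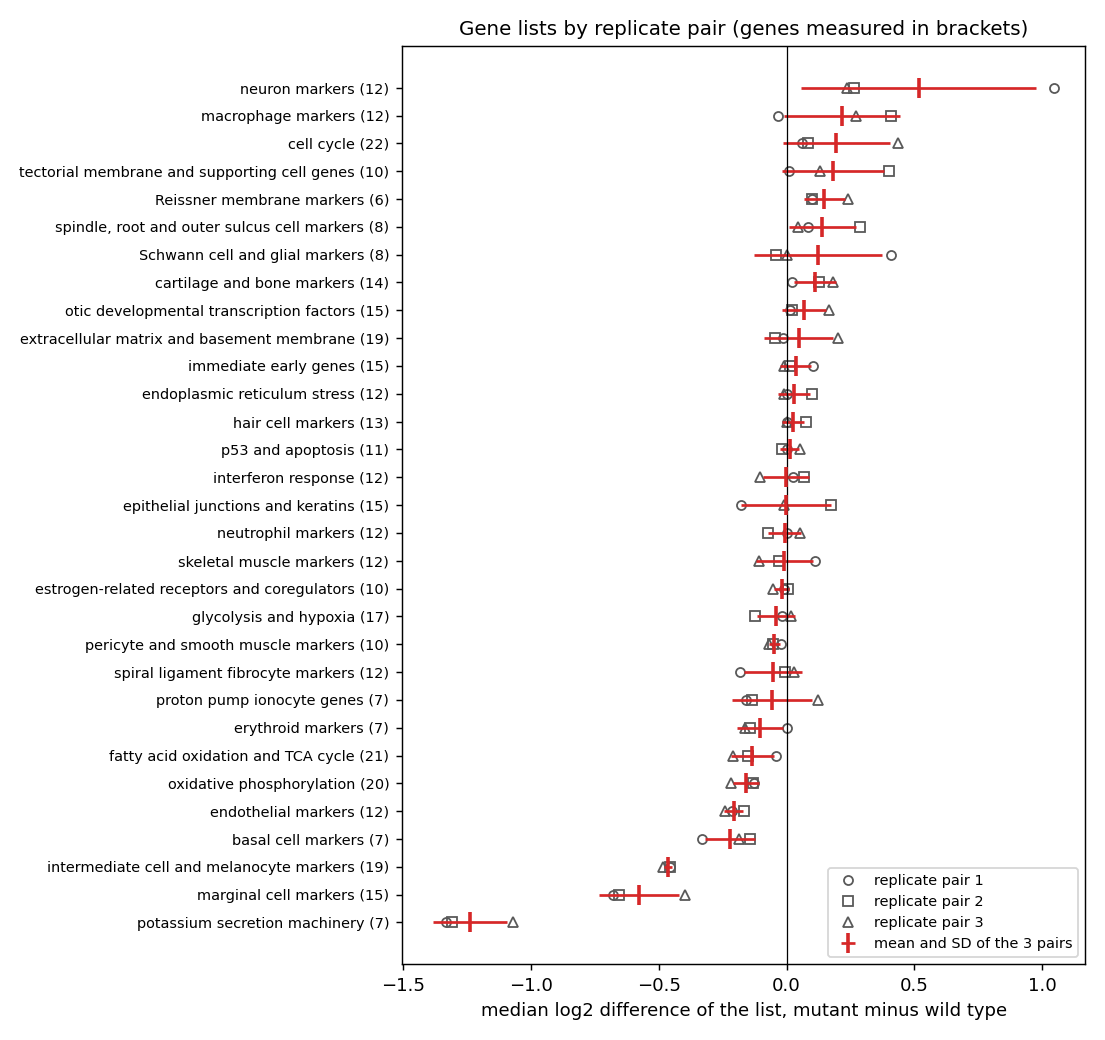
Median log2 difference (horizontal axis, mutant minus wild type) of each of 31 gene lists in each replicate pair, with red bars for the mean and SD of the 3 pairs. The potassium secretion, marginal cell and pigment cell lists lie below 0 in every pair, with means of -1.24, -0.58 and -0.46, while the neuron list is spread from 0.24 to 1.05.

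No gene near Esrrb passed. Of 294 genes within 20 Mb of Esrrb on its chromosome, 0 passed in either fit, against 1 of 17733 others unpaired and 27 of 17733 paired (Fisher's exact test, two-sided, p = 1 for both). So few genes passed that 0 of 294 was likely by chance alone. The test therefore cannot exclude differences carried by a chromosome segment linked to Esrrb. Y-linked genes and Xist, which track the sex of the pooled mice, varied between pairs: Eif2s3y differed by 0.79, -1.13 and -0.16 and Xist by -0.23, 0.70 and 0.40 in pairs 1 to 3. Other Xist probe sets differed by -0.21, 0.83 and 1.85 and by -0.07, 0.90 and 0.94 in these pairs.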

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

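The alternatives within the paired fit, including those without each pair, were chosen after seeing the data. The replicate block moved the counts from 3 to 42 probe sets and from 1 to 27 genes, ended the calls of the cartilage and bone and fibrocyte lists, and changed no other list call. The 27 genes of the paired fit differed in the same direction under all settings that measured them. All 27 had the same sign in the 3 pairs of these same arrays, so the settings could hardly reverse them, and this is no independent support. In the unpaired fit, quantile normalization and median centring each gave 1 higher and 1 lower probe set in place of 1 and 2, and 1 gene, Igsf1, in place of Kcne1. Trend and robust options gave 2 genes and the mean of a gene's probe sets gave 3. Array weights gave 42675 probe sets and 17245 genes, with Esrrb at 0.023; 1 fit of the weights warned of not converging, and these counts are not usable as calls. Leaving out 1 array gave 2 to 11 probe sets, 1 to 6 genes and 11 to 15 lists, and an Esrrb difference of -0.27 to 0.19, which turned positive without wild-type replicate 2 (0.19) and without mutant replicate 1 (0.053). Over these, list medians ran from -0.24 to 0.54 for cartilage and bone, -0.35 to 0.39 for fibrocytes and -0.56 to 0.20 for endothelium, and the test turned without wild-type replicate 1 for the first and without mutant replicate 1 for the others; the median of all probe sets itself was -0.19 and 0.19 then, and 0.23 without wild-type replicate 2, since unequal pairs were compared. In the paired fit, array weights gave 77 probe sets and 49 genes, the mean of a gene's probe sets gave 58 genes, and an adjusted p under 0.01 left 6 probe sets and 5 genes, by its own construction. Leaving out a pair gave 0 to 7 probe sets, 0 to 4 genes and 11 to 13 lists, with fewer samples and 1 residual degree of freedom, and an Esrrb difference of -0.15 to 0.049, positive without replicate 2. Camera with an estimated correlation gave 1 list unpaired and 0 paired, and fry 0 and 1. For the other moves the cause was not tested. Of 235 comparisons of named genes with the unpaired fit, 47 newly passed, 16 of them with array weights and 31 in the other 218, 2 no longer passed (Kcne1 under those 2 settings) and 0 reversed; of 167 with the paired fit, 50 no longer passed. Of 210 comparisons of lists unpaired 28 no longer passed, 6 of them with array weights, and 3 turned; of 150 paired 4 no longer passed. Windows of 10 and 50 Mb around Esrrb also held 0 genes that passed. Signal over background is not given with the deposited values, so what it limits for weakly expressed genes was not tested.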

Other observations

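The tests of explanations in this part were chosen only after the results were seen. Beyond the genes selected by rule, the 24 genes that fell in the paired fit included F3, the tissue factor gene (-1.60), Fads6 (-1.50), Hs3st6, a heparan sulfate sulfotransferase gene (-1.32), Mt3, a metallothionein gene (-1.26), Adm, the adrenomedullin gene (-0.89), and Slc38a5, an amino acid transporter gene on the X chromosome (-1.16); these were picked after their values were seen. A less expressed probe set of Kcnq1ot1, the transcript antisense to Kcnq1, also picked after its values were seen, fell by 1.28 (SD 0.17 of 3 pairs), while its best expressed probe set differed by 0.080 and did not pass (adjusted p = 0.867). The best expressed Kcne1 probe set moved from the 88.9 to 96.2 percentile of all probe sets on the wild-type arrays to the 21.8 to 38.2 percentile on the mutant arrays.

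Reissner membrane markers moved apart. In the paired fit, adjusted over the list alone, 5 of 6 passed, 3 higher and 2 lower, against 0 in the unpaired fit and 0 over all probe sets in either. Oc90 differed by 1.03 ± 0.32 and Enpep by -0.90 ± 0.22 (adjusted p = 0.156 and 0.112), and Wnk4, named after its values were seen, by -1.11. Among epithelial genes 3 passed when adjusted over the list alone in the paired fit, 1 higher and 2 lower, and 0 over all probe sets. Named after their values were seen, they were Krt7 (-1.12), the tight junction gene Ocln (-0.69) and the claudin gene Cldn8 (0.32), with adjusted p = 0.261, 0.257 and 0.369 over all probe sets.

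The number of probe sets called went from 3 without pairs to 42 with them. A level offset between separately normalized pairs is not the whole cause, since quantile normalization of all 6 arrays left 2 probe sets unpaired. Pair 1, with its wide Gapdh 3' to 5' difference, is not the whole cause either, since the difference between replicates 2 and 3 correlated at 0.688 between the genotypes across probe sets, which are not independent. Values summarized separately for each pair may have tied same-numbered arrays together, as at least 1185 probe sets held equal values within a pair and 0 in other pairs. Quantile normalization left the lowest correlation of deviations within a pair at 0.740, which decides nothing, since it acts on values already summarized; the tests left this cause open. Whether tissue or RNA was handled in pairs is not given in the sources used here. Among the 4 divisions that part all 3 pairs the paired fit gave 42 probe sets and 27 genes for the genotypes and at most 0 and 0 for the others, and 13 lists against at most 10; in each case 1 of 4 was as large, and 4 divisions are too few for a share under 0.05.

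The same limit holds for the unpaired fit, where the 10 divisions of the 6 arrays are too few for a share under 0.05. For probe sets 2 of 10 were as large, with 3 for the genotypes and 4055 for the highest other, for genes 2 of 10 with 1 against 1076, and for lists 3 of 10 with 15 against 17. The division with 4055 probe sets set wild-type replicate 1, mutant replicate 1 and mutant replicate 3 against the rest; the cause of its count was not tested.

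Pigment cell genes were lower in each pair, and the list medians of pairs 2 and 3 were -0.45 or lower, which argues against pair 1 as the sole source. A smaller share of stria in the mutant dissections would raise the markers of other tissues alike. Over 8 such lists the means did not move apart by more than shuffled list labels gave (permutation p = 0.0839, 100000 shuffles). The means of fibrocyte (-0.05 ± 0.11) and muscle markers (-0.01 ± 0.11) lay below 0 by less than their SD. The fibrocyte list also holds Gjb6 and Gjb2, which were lower and are basal cell markers too, so it does not stand for other tissue alone. A smaller share of stria therefore cannot be told apart from a change within pigment cells. The potassium secretion list median differed from that of the pigment cells by -0.77 ± 0.16 (mean and SD of 3 pairs, 1 shared member, Kcnj10). This gap does not decide whether the share of stria was smaller, since the 2 lists need not be equally confined to stria. Marginal cell markers had pair medians of -0.68, -0.65 and -0.40, against -0.46, -0.45 and -0.48 for pigment cells. A candidate explanation for the gap, not tested here, is a change of expression within marginal cells that follows the genotype.

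Of the 3 genes that rose in the paired fit, Slitrk4 and Igsf1 are X-linked. Il1rapl2, also X-linked and picked after its values were seen, passed by 1 probe set (0.81, adjusted p = 0.0466), while its best expressed probe set did not (0.39, adjusted p = 0.520). At an unadjusted p under 0.01 in the paired fit 15 of 193 higher genes were on the X chromosome (7.77%, against 3.42% of 18028 placed genes), and 4 of 263 lower genes. Adjusted over 40 tests of chromosomes and directions, Fisher's exact p was 0.154 there, 0.00160 at an unadjusted p under 0.05 and 1 at a limit of 0.001, so chance may or may not account for it, and genes are not independent replicates. Unequal sex of the pools is not the whole cause, since the pair medians of the Y-linked genes ran from 0.79 to -1.13 while Slitrk4 and Igsf1 were higher in every pair. Linked passenger alleles on the X chromosome were not tested.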
